A study of Mus musculus with 14 samples.

How the data were processed

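RNA from 14 mouse hearts was profiled on Affymetrix arrays, from 5 fed mice, 5 mice fasted for 24 h and 4 mice on a ketogenic diet for 4 weeks. Per the labels, all mice were male C57Bl/6. The fed and fasted mice were born in germ-free isolators, were given a microbiota at weaning and were 6 to 10 weeks old. The ketogenic mice were free of specific pathogens, changed diet at 8 weeks and were 12 weeks old. The RNA of the first 10 arrays is labelled polyA and that of the ketogenic arrays total, although both label protocols start from 12 µg of total RNA. Scan dates are not given in the sources used here, so batches of scanning could not be tested, and the ketogenic arrays hold samples of 1 group only.

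The deposited values are an intensity per probe set and array on a linear scale. On every array the mean of the values was the same once the lowest and highest 2% were left out. This was read here as a scaling applied by the authors, and no normalization between arrays beyond it was assumed. The authors' notes name MAS5 for the fed and fasted arrays and Affymetrix Expression Console for the ketogenic arrays. Versions, parameters and the algorithm used within Expression Console are not given in the sources used here. Detection calls were not used here. The number of arrays and the signal level of each probe set limit the precision.

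Probe sets were joined to genes with the platform annotation, which gave 34958 probe sets with a single gene symbol. Another 932 with several symbols, 9211 with none and 64 control probe sets were left out of the gene tests. Of the single-symbol probe sets, 34754 were found by Entrez ID in a RefSeq gene table of assembly GRCm38.p6, used for names only, and 0 symbols changed. Each of 18193 genes was represented by its probe set with the highest mean signal. Genes were tested if their signal lay above the median of an array on at least 4 of the 14 arrays, which left 12597 genes and removed 5596 dim ones, Fgf21 among them with mean signals of 45.9, 60.3 and 53.5 in fed, fasted and ketogenic hearts. Cpt1b had no probe set with a single symbol and was not tested.

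All 14 arrays were quantile normalized together and log2 transformed without an offset in R 4.3.3 with limma 3.58.1. Linear models with moderated variances and an intensity trend were fitted to the 10 fed and fasted arrays for fasted vs fed, and to all 14 arrays for ketogenic vs fed and ketogenic vs fasted. P-values were adjusted by the Benjamini-Hochberg method over the tested genes. A gene was called at an adjusted p below 0.05, and counted again at a change of at least 2-fold. Adjusted p-values beside a gene are from limma. Means with SD are of the linear normalized signal, while log2 fold changes with SE are from the models, and signal units are those after normalization.

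Gene lists (29 of pathways and 15 of cell type markers) were written before the data were examined, as were the groups, comparisons, thresholds, panel of 20 genes, rule for named genes and all alternatives except those named as chosen later. The 44 lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 44 lists, and again with an estimated correlation and with fry. Unless stated otherwise, an adjusted p beside a list is camera's with the preset correlation. A p from fry tests whether the genes of a list move, on balance, in 1 direction, without comparing them with other genes. Named genes were the 8 largest rises and 8 largest falls with separate groups in each comparison, the panel, and up to 4 members with the smallest p of each described list. Two-sided exact permutation tests compared marker means and control probe sets between groups, adjusted over the measures of a comparison.

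Alternatives covered the values as deposited, centring on the array median or 75th percentile, normalization within each processing note, offsets, filters on dim probe sets, the mean of all probe sets of a gene, leaving out probe sets that may share sequence with other transcripts, variance settings, array weights, the set of arrays in the model, a replicate block, a stricter threshold and leaving out each array. The probe sets that may share sequence with other transcripts are those ending in _x_at, _s_at or _a_at, and these may be transcripts of the same gene. The probe set of each gene and the tested genes stayed the same under other scalings, offsets and left-out arrays. This was chosen after seeing the data, when choosing probe sets anew under each scaling had reversed some genes by a change of probe set. A covariate for the atrial marker mean, and leaving out fed samples 1 and 5 together, were added after the data were seen. Replicate numbers do not pair samples, since the correlation of samples with the same number, after removal of group means, was -0.0163 to 0.018. Each comparison was also repeated on 100 splits of its samples. The method was tested on simulated data with 200 of 12597 genes changed, where it recovered 54.1%, 68.7% and 69.7% of changes of 1 on the log2 scale in the design of the 3 comparisons, with 6.03%, 11.7% and 4.69% of calls false.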

Results

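Transcript levels were measured in 14 mouse hearts on Affymetrix arrays. The hearts came from 5 fed mice on a carbohydrate diet, 5 mice after a 24 h fast and 4 mice on a ketogenic diet (very high in fat and low in carbohydrate) for 4 weeks. Fed and fasted mice were born germ-free, received a gut microbiota at weaning and were 6 to 10 weeks old. Mice on the ketogenic diet were 12 weeks old, were housed free of specific pathogens and their arrays carry another processing note, so that diet, age, housing and processing coincide. The labels number the samples within each group and say nothing more about which animal each heart came from, so the p-values measure the spread between these samples. The number of arrays and the signal level of each probe set limit the precision.

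The 3 groups separated on the first 2 principal components, which held 33.7% and 21.5% of the variance. The ketogenic arrays stood at 61.5 ± 1.66 on the first component (SD, n = 4), against -14.5 ± 7.29 for fed and -34.8 ± 3.23 for fasted arrays (SD, n = 5 each). Before normalization the median probe set signal was 167 ± 23.1 in fed, 133 ± 9.09 in fasted and 94.2 ± 4.06 in ketogenic arrays. Markers of atrial tissue differed between the groups, with a mean log2 signal of 10.1 ± 1.27 in fed, 12.86 ± 0.29 in fasted and 7.93 ± 0.20 in ketogenic hearts. Fed hearts alone ranged from 8.74 to 12.11 on this mean. Control probe sets for 18S ribosomal RNA had a mean log2 signal of 8.56 ± 0.53 in fed, 11.38 ± 0.62 in fasted and 9.31 ± 0.36 in ketogenic hearts. The signal ratio of 3' to 5' probe sets of Actb, a measure of RNA integrity, was 1.21 in fed, 1.13 in fasted and 1.59 in ketogenic hearts. That of Gapdh was 0.823 in fed, 0.989 in fasted and 0.79 in ketogenic hearts. Between fasted and fed hearts the Gapdh ratio differed (exact permutation test, adjusted p = 0.0238) and the Actb ratio did not (adjusted p = 0.235), while between ketogenic and fed hearts Actb differed (adjusted p = 0.0204) and Gapdh did not (adjusted p = 0.0918). Directions are given after quantile normalization of all arrays. Centring on the array median instead moved the median log2 fold change of all genes from 0.0033 to 0.25 (fasted vs fed), from -0.08 to 0.55 (ketogenic vs fed) and from -0.13 to 0.23 (ketogenic vs fasted).

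**Figure D1:**
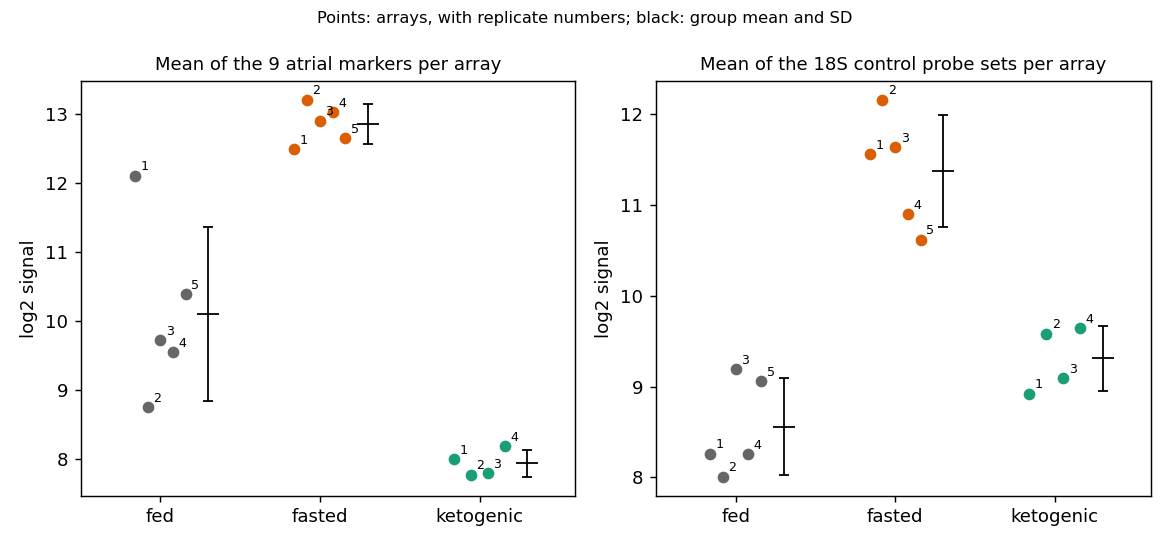
Mean log2 signal of the atrial markers and of the 18S ribosomal RNA control probe sets on each of the 14 arrays, 1 point per array. Atrial markers range from 8.74 to 12.11 in fed, from 12.49 to 13.21 in fasted and from 7.77 to 8.19 in ketogenic hearts.

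After 24 h without food, the heart carried more transcript of genes that respond to glucocorticoids, of FoxO and PPAR target genes and of genes of fat oxidation and lipid droplets. With an estimated correlation between genes, fat oxidation did not pass (adjusted p = 0.0782) and the others did. Irs2, an adaptor of the insulin receptor, rose from 30.8 ± 4.96 to 712 ± 251 signal units (SD, n = 5 each), a log2 fold change of 4.48 ± 0.32 (SE, adjusted p = 8.82e-08). Its fed signal is dim, so the size of the fold is uncertain, and with an offset of the array median it was 2.32. Plin2, a coat protein of lipid droplets, rose from 3248 ± 256 to 8731 ± 782, a log2 fold change of 1.43 ± 0.08 (adjusted p = 7e-09). Tfrc, the transferrin receptor that takes up iron, fell from 6999 ± 910 to 429 ± 131, a log2 fold change of -4.07 ± 0.17 (adjusted p = 5.15e-10), and its 3 other probe sets gave -3.75 to -1.99. The comparison asked how the heart responds to a fast, and 4262 of 12597 genes changed (2218 higher, 2044 lower), 1017 of them at least 2-fold (529 higher, 488 lower). This split depends on the scaling: centred on the array median, 83.1% of the called genes were higher, against 52% after quantile normalization.

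Of 22 genes that respond to glucocorticoids, 19 rose, 0 fell and 3 did not pass the test, with a median log2 fold change of 1.19 (camera adjusted p = 2.45e-12). Adjusted over the list alone, 20 rose. The metallothioneins Mt1 and Mt2 rose by 1.70 and 2.66 on the log2 scale, Fkbp5, a chaperone of the glucocorticoid receptor, by 2.33, and Cdkn1a, an inhibitor of the cell cycle, by 1.52. Among 29 FoxO targets, ubiquitin ligases and autophagy genes, 17 rose, 2 fell and 10 did not pass (median 0.54, adjusted p = 1.03e-06), and adjusted over the list alone 18 rose and 2 fell. Bnip3, which takes part in the removal of mitochondria, rose by 1.22, Eif4ebp1, a repressor of translation, by 1.07 and Fbxo31 by 0.98. Genes of oxidative stress defence rose in 18 of 28 cases, fell in 1 and did not pass in 9 (median 0.52, adjusted p = 1.94e-07), or in 19 and 1 adjusted over the list alone. Gsta4 and Gstm1, glutathione transferases, rose by 1.41 and 0.73. All 3 lists stayed past the threshold with an estimated correlation (adjusted p = 0.005 for each).

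Several lists of fat use rose as groups. In the PPAR-responsive list, 18 of 24 genes rose, 1 fell and 5 did not pass (median 0.63, adjusted p = 1.12e-08, and adjusted p = 0.005 with an estimated correlation), and adjusted over the list alone 19 rose and 1 fell. Acot1 and Acot2, thioesterases of long-chain acyl-CoA, rose by 2.00 and 1.40, and Angptl4, an inhibitor of lipoprotein lipase, rose from 2199 ± 536 to 6016 ± 686, a log2 fold change of 1.48 ± 0.14 (adjusted p = 1.57e-06). With the mean of all its probe sets, Angptl4 no longer passed (0.68, adjusted p = 0.354), but that mean takes in probe sets too dim for the filter. Of 26 genes of triglyceride storage and lipolysis, 15 rose, 2 fell and 9 did not pass, with the same counts adjusted over the list alone (median 0.36, adjusted p = 7.15e-05, and adjusted p = 0.044 with an estimated correlation). Pnpla2, the adipose triglyceride lipase, rose by 1.18, and Plin4 by 1.14, while Lpin1, a phosphatidate phosphatase, fell by 1.25 on the log2 scale. White adipocyte markers averaged 1.56 higher in the same hearts, and with the atrial marker mean as a covariate the median fold of the called members went from 0.90 to 0.62 for this list and from 1.05 to 0.73 for the PPAR-responsive list. In mitochondrial fatty acid oxidation 14 of 22 genes rose, 0 fell and 8 did not pass (median 0.25, adjusted p = 2.03e-06), and adjusted over the list alone 15 rose and 1 fell. Its adjusted p = 0.0782 with an estimated correlation. Mlycd, which breaks down the malonyl-CoA that restrains fat import into mitochondria, rose by 1.33 ± 0.08, Eci1 by 0.78, Decr1 by 0.73 and Eci2 by 0.65. Peroxisomal lipid oxidation did not pass, with 7 rises, 4 falls and 6 not passing among 17, or 8 and 4 adjusted over the list alone (median 0.40, adjusted p = 0.127), but passed under 3 of the 4 other scalings. Cpt1a rose by 0.51 ± 0.14 (adjusted p = 0.0122) but gave 0.02 with the mean of all its probe sets. The fat uptake protein Cd36 gave 0.04 (adjusted p = 0.729) and 0.82 when centred on the array median (adjusted p = 2.67e-05). Ucp3 gave 0.24 (adjusted p = 0.294) and 0.65 with that centring (adjusted p = 0.00593), and Ppara 0.30 (adjusted p = 0.168).

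Genes of glucose use were lower after the fast. Of 21 genes of glucose uptake and glycolysis, 11 fell, 1 rose and 9 did not pass, with the same counts adjusted over the list alone (median -0.20, adjusted p = 2.65e-03, and adjusted p = 0.267 with an estimated correlation). Slc2a4, the insulin-responsive glucose transporter, fell from 14435 ± 1834 to 9022 ± 1174, a log2 fold change of -0.68 ± 0.10, Hk1 fell by 0.81, Pfkfb2 by 1.24 and Pgk1 by 0.59 on the log2 scale. Of 13 genes of pyruvate dehydrogenase and its regulation, 6 fell, 3 rose and 4 did not pass, also adjusted over the list alone (median -0.23, adjusted p = 3.47e-02, and adjusted p = 0.333 with an estimated correlation). The subunits Dld and Pdhb fell by 1.16 and 0.69 and the pyruvate carrier Mpc1 by 0.84 on the log2 scale. Pdk4, the kinase that switches the complex off, rose from 19508 ± 6249 to 40395 ± 4474, a log2 fold change of 1.11 ± 0.17 (adjusted p = 1.73e-04). In the tricarboxylic acid cycle 9 of 18 genes fell, 2 rose and 7 did not pass, or 10 fell and 3 rose adjusted over the list alone (median -0.17, adjusted p = 7.95e-03, and adjusted p = 0.267 with an estimated correlation). Among them were Ogdh at -0.47, Sdhd at -0.32 and Suclg2 at -0.31. The direction of these 3 lists turns with the scaling of the arrays: centred on the array median, their medians were 0.30, 0.27 and 0.55, and Pgk1, Pdhb, Ogdh, Sdhd and Suclg2 gave 0.20, 0.02, 0.27, 0.44 and 0.19. The tricarboxylic acid cycle list was then called higher (adjusted p = 4.06e-04), as it was in the values as deposited (0.23) and when centred on the 75th percentile (0.34). Hk2, with -0.43 ± 0.10 (adjusted p = 3.42e-03), gave 0.08 when centred on the array median, and Slc2a4 -0.13 (adjusted p = 0.53). Without fed sample 2 or fasted sample 2, the pyruvate dehydrogenase list did not pass (adjusted p = 0.062 and 0.0572).

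Ketone body genes did not differ as a group from other genes after the fast, and their direction turned with the scaling. Of 6, 0 rose, 2 fell and 4 did not pass (median -0.21, but 0.15 when centred on the array median, adjusted p = 0.186), with 2 falls adjusted over the list alone. Oxct1, the enzyme that activates acetoacetate for use as fuel, fell from 49397 ± 2695 to 22503 ± 1850, a log2 fold change of -1.14 ± 0.06 (adjusted p = 6.91e-09), and its other probe sets gave -3.61 to -0.58. Slc16a1, a transporter of lactate and ketone bodies, fell from 9853 ± 562 to 5345 ± 561, a log2 fold change of -0.89 ± 0.08 (adjusted p = 7.71e-07). With the mean of all its probe sets Slc16a1 gave 0.015, and centred on the array median -0.37 (adjusted p = 0.0649). That mean gives equal weight to a dim probe set (mean signal 61.9, against 9438), which was not called (0.92, adjusted p = 0.467). Bdh1, which interconverts the ketone bodies, gave 0.35 ± 0.22 (adjusted p = 0.236), and Acat1 had 18814 ± 998 in fed and 18801 ± 322 in fasted hearts (adjusted p = 0.995).

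Stress genes went in separate directions. Of 29 genes of the unfolded protein response and heat shock, 12 fell, 4 rose and 13 did not pass, also adjusted over the list alone (median -0.25, adjusted p = 1.15e-02, and adjusted p = 0.251 with an estimated correlation). The endoplasmic reticulum chaperones Hsp90b1 and Calr fell by 1.47 and 1.20 and Hspb7 by 0.66 on the log2 scale, while Herpud1 rose by 0.98. Centred on the array median, this list had a median of 0.10 and was not called, and Hspb7 also gave 0.10. In the amino acid and integrated stress response 6 of 20 genes rose, 0 fell and 14 did not pass, or 7 rose and 0 fell adjusted over the list alone (median 0.25, adjusted p = 1.57e-02, and adjusted p = 0.082 with an estimated correlation). Ppp1r15a gave 1.42, Nupr1 1.84 and Psat1, of serine synthesis, 1.55. Immediate early genes rose in 9 of 21 cases, fell in 1 and did not pass in 11, also adjusted over the list alone (median 0.65, adjusted p = 5.82e-03, and adjusted p = 0.515 with an estimated correlation). Klf6 gave 2.62, Btg2 2.07, Zfp36 1.35 and Ccn1 1.01. Without probe sets that may share sequence with other transcripts, the immediate early list did not pass (median 0.45, adjusted p = 0.144), nor did the unfolded protein list (-0.10, adjusted p = 0.526).

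Markers of 2 other tissues were higher in the fasted hearts as well. Of 9 atrial markers 8 rose, 0 fell and 1 did not pass, also adjusted over the list alone (median 2.75, adjusted p = 4.24e-05, and adjusted p = 0.267 with an estimated correlation). Bmp10 rose by 3.86, Dkk3 by 2.75, Nppa by 2.37 and Stard10 by 1.94. Sln, an atrial regulator of the calcium pump, rose from 5616 ± 10250 to 34232 ± 6764, a log2 fold change of 4.38 ± 0.78 (adjusted p = 5.27e-04). Of 7 white adipocyte markers 6 rose, 0 fell and 1 did not pass, also adjusted over the list alone (median 2.00, adjusted p = 2.65e-03, and adjusted p = 0.0782 with an estimated correlation), among them Adipoq at 2.14, Car3 at 2.13, Pparg at 2.00 and Lipe at 1.48. Erythroid and blood markers averaged 0.59 higher (exact permutation test, adjusted p = 0.0409), with 1 rise, 0 falls and 5 not passing among 6, also adjusted over the list alone, and did not pass as a list (median 0.44, adjusted p = 0.151). Ventricular cardiomyocyte markers averaged 0.15 lower (exact permutation test, adjusted p = 0.0238), with 0 rises, 5 falls and 7 not passing among 12, also adjusted over the list alone, and did not pass as a list (adjusted p = 0.065). Their median was -0.06, and 0.90 when centred on the array median. Further large rises were in Mlana (4.68), Stk11ip (4.59), Gm20346 (4.04), Serpina3n (3.82), a protease inhibitor of the acute phase, and Fut2 (3.82). Further large falls were in Ush1c (-3.45), F8a (-3.20), Gpr174 (-3.02), Mycn (-2.89), Serpina1c (-2.84), Gm15423 (-2.75) and Exoc3l2 (-2.73). With an offset of the array median, which keeps dim signals from inflating folds, the 8 largest rises gave 1.13 to 4.17 and the 8 largest falls -3.68 to -0.65. Another probe set pointed the opposite way for F8a (1.16) and Mycn (0.38). Serpina1c did not pass when any 1 fed sample was left out (adjusted p = 0.0552 to 0.0826), nor did Ush1c without fed sample 4 (adjusted p = 0.0508). Panel genes also included Fasn, of fatty acid synthesis, which rose by 0.68 ± 0.16 (adjusted p = 4.26e-03, but 0.37 and adjusted p = 0.541 with the atrial marker mean as a covariate), Slc2a1 at 0.24 (adjusted p = 0.176) and Ppargc1a at -0.02 (adjusted p = 0.938), whose 4 other probe sets gave -1.69 to -0.72 (mean of all -1.01, adjusted p = 2.15e-06). With the atrial marker mean as a covariate, a choice made after the data were seen, 1181 genes passed in place of 4262, Pdk4 gave 0.63 (adjusted p = 0.259), and the glycolysis, pyruvate dehydrogenase and tricarboxylic acid cycle lists did not pass (adjusted p = 0.105, 0.105 and 0.119). The median fold of the called members of these 3 lists went from 0.46 to 0.35, from 0.56 to 0.63 and from 0.26 to 0.23, and their median SE from 0.08 to 0.16, from 0.08 to 0.14 and from 0.06 to 0.11. The 18S probe sets were 7.05-fold higher in fasted than in fed hearts, in all 5 fasted samples (exact permutation test, two-sided, p = 0.00794, the smallest that 252 splits allow, adjusted p = 0.0238).

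**Figure D2:**
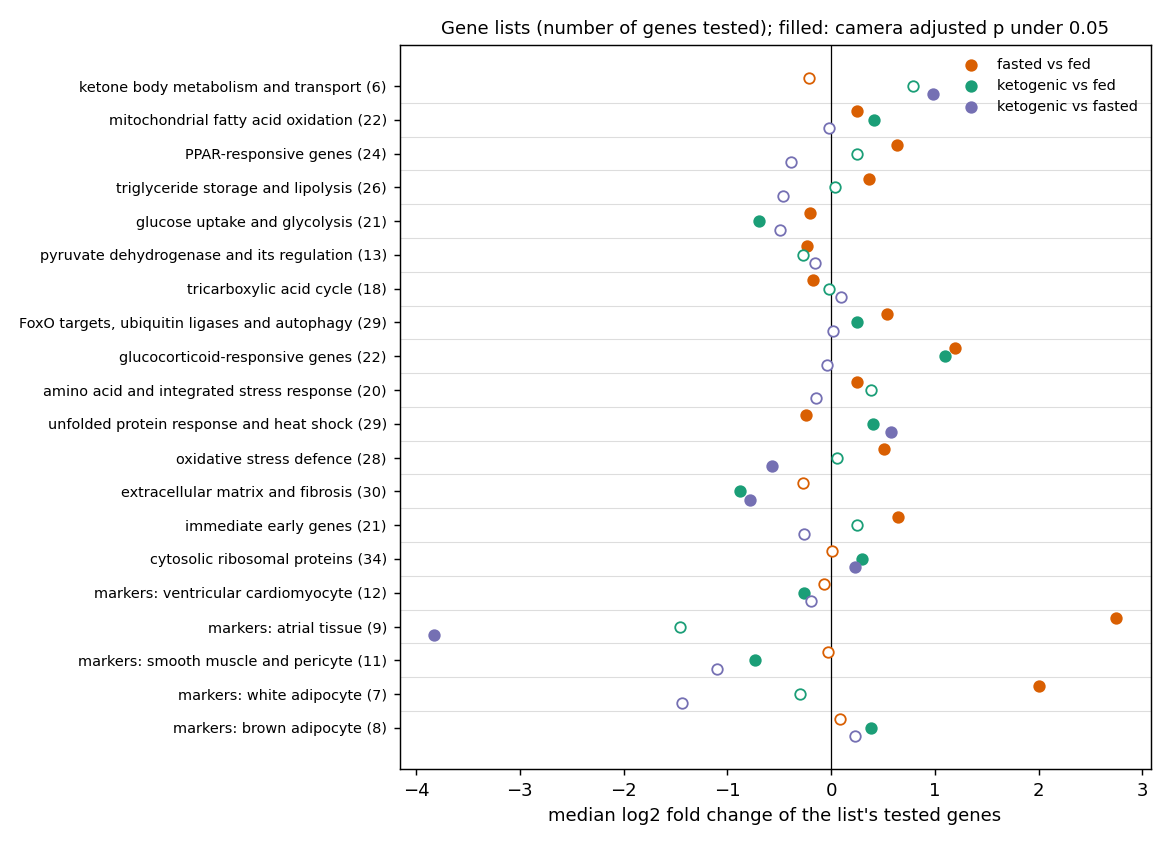
Median log2 fold change of each gene list that passed in at least 1 of the 3 comparisons, with filled points for a camera adjusted p below 0.05 and the number of tested genes in brackets. The median of the glucocorticoid-responsive list is 1.19 after the fast and 1.10 on the ketogenic diet, while that of the extracellular matrix list is -0.88 on the ketogenic diet.

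On the ketogenic diet the heart carried more transcript of genes of fat oxidation, of glucocorticoid-responsive genes and of ribosomal proteins than fed hearts, and less of glycolysis and of the extracellular matrix. With an estimated correlation only the glucocorticoid list of these passed (adjusted p = 0.0335), and centred on the array median the glycolysis and matrix medians turned to 0.23 and 0.13. Ppargc1a, a coactivator that drives mitochondrial genes, rose from 1995 ± 67.3 to 19413 ± 2334 signal units (SD, n = 5 and n = 4), a log2 fold change of 3.28 ± 0.12 (SE, adjusted p = 2.38e-13), and its other probe sets gave 2.28 to 3.46. Pdk4 rose to 68606 ± 9103, a log2 fold change of 1.87 ± 0.18 (adjusted p = 6.68e-08), while Slc2a4 fell to 3960 ± 149, a log2 fold change of -1.86 ± 0.09 (adjusted p = 2.43e-11), and its other probe set gave -0.73. The comparison asked how the heart differs after 4 weeks of the ketogenic diet, and 6283 of 12597 genes changed (2705 higher, 3578 lower), 2055 of them at least 2-fold (842 higher, 1213 lower). Centred on the array median instead, 85.2% of the called genes were higher, against 43.1% after quantile normalization. Of the genes called higher 82.2% were called higher under all 4 other scalings, and of those called lower 30.1% were called lower under all 4.

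In mitochondrial fatty acid oxidation 14 of 22 genes rose, 3 fell and 5 did not pass, also adjusted over the list alone (median 0.42, adjusted p = 2.92e-04, and adjusted p = 0.145 with an estimated correlation). Etfdh, which passes electrons from fat oxidation to the respiratory chain, rose by 1.21, Decr1 by 0.92 and the long-chain dehydrogenase Acadl by 0.60. Cd36 rose from 26323 ± 2824 to 46271 signal units, a log2 fold change of 0.82 ± 0.07 (adjusted p = 4.13e-08), and Ppara by 1.51 ± 0.15 (adjusted p = 1.2e-07). Peroxisomal lipid oxidation gave 9 rises, 3 falls and 5 not passing among 17, also adjusted over the list alone, and passed under the 4 other scalings but not here (median 0.29, adjusted p = 0.0852). The PPAR-responsive list did not pass: 12 of 24 genes rose, 7 fell and 5 did not pass (median 0.25, adjusted p = 0.0754), and adjusted over the list alone 12 rose and 8 fell. Within it Acot1 rose by 1.68 (adjusted p = 2.09e-07), whereas Angptl4 fell to 981 ± 405, a log2 fold change of -1.22 ± 0.21 (adjusted p = 1.0e-04), and was not called with the mean of all its probe sets (-0.25). Ucp3, an uncoupling protein, gave -1.04 (adjusted p = 7.68e-05) and -0.11 when centred on the array median (adjusted p = 0.612). Cpt1a gave -0.74 (adjusted p = 2.19e-04), but 0.46 with the mean of all its probe sets and 0.19 when centred on the array median. Its other, dim probe sets were not called (0.86 and 1.27, adjusted p = 0.0647 and 0.0866). Plin2 gave 0.04 (adjusted p = 0.721) after quantile normalization and was called higher under each of 4 other scalings (0.25 to 1.06).

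Ketone body genes gave 4 rises and 1 fall among 6, with 1 that did not pass, also adjusted over the list alone, without passing as a group (median 0.79, adjusted p = 0.0746). Slc16a1 rose to 18348 ± 351, a log2 fold change of 0.90 ± 0.07 (adjusted p = 1.02e-08), Bdh1 rose by 1.21 ± 0.25 (adjusted p = 4.89e-04) and Acat1 by 0.55 ± 0.05 (adjusted p = 3.99e-08). Oxct1 fell to 32233 ± 1183, a log2 fold change of -0.61 ± 0.06 (adjusted p = 1.36e-07), but gave 0.12 when centred on the array median. Its other probe sets gave -1.55 to -0.21.

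Of 21 genes of glucose uptake and glycolysis, 13 fell, 3 rose and 5 did not pass, also adjusted over the list alone (median -0.69, adjusted p = 1.06e-03, and adjusted p = 0.149 with an estimated correlation). Pgk1 fell by 1.54, Pkm, the last enzyme of glycolysis, by 1.12 and Ldhb, a lactate dehydrogenase, by 0.94 on the log2 scale. Centred on the array median, the list had a median of 0.23 and was not called. Slc2a1 gave -0.80 (adjusted p = 4.22e-05), but 0.38 with the mean of all its probe sets. Hk2 at -0.25 (adjusted p = 4.37e-02) and Fasn at -0.39 (adjusted p = 4.63e-02) turned to 0.86 and 0.21 when centred on the array median, and without ketogenic sample 2 or fed sample 1 respectively they gave -0.22 (adjusted p = 0.116) and -0.32 (adjusted p = 0.111).

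Genes that respond to glucocorticoids rose in 17 of 22 cases, fell in 1 and did not pass in 4 (median 1.10, adjusted p = 2.40e-08, and adjusted p = 0.0335 with an estimated correlation), or in 18 and 1 adjusted over the list alone. Sgk1, a kinase induced by steroid hormones, rose by 2.47, Glul, the glutamine synthetase, by 1.82, Errfi1 by 1.73 and Mt1 by 1.01. Among FoxO targets, ubiquitin ligases and autophagy genes 16 of 29 rose, 5 fell and 8 did not pass, or 16 rose and 6 fell adjusted over the list alone (median 0.25, adjusted p = 9.43e-03, and adjusted p = 0.115 with an estimated correlation). Trim63, a muscle ubiquitin ligase, rose by 1.29, Bnip3 by 1.33 and Map1lc3b by 1.02, while Map1lc3a fell by 1.10 on the log2 scale. With the mean of all probe sets the FoxO list did not pass (median 0.14, adjusted p = 0.0579). Of 29 genes of the unfolded protein response and heat shock, 18 rose, 6 fell and 5 did not pass, or 19 rose and 6 fell adjusted over the list alone (median 0.41, adjusted p = 3.25e-03, and adjusted p = 0.145 with an estimated correlation). Among them were Hsp90aa1 at 1.55, Herpud1 at 1.39, Dnajb9 at 1.05 and Calr at -0.92 (0.21 when centred on the array median). Cytosolic ribosomal proteins rose in 21 of 34 cases, fell in 7 and did not pass in 6, also adjusted over the list alone (median 0.30, adjusted p = 9.62e-04, and adjusted p = 0.145 with an estimated correlation). Rps14 rose by 0.90, Rps29 by 0.80, Rpl11 by 0.86 and Rpl8 by 0.93. Rps29 gave -0.14 in the values as deposited.

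Genes of the extracellular matrix and fibrosis were lower on the ketogenic diet. Of 30, 20 fell, 2 rose and 8 did not pass, or 20 fell and 3 rose adjusted over the list alone (median -0.88, adjusted p = 8.81e-06, and adjusted p = 0.321 with an estimated correlation). The collagens Col15a1, Col6a1 and Col4a2 fell by 2.58, 1.42 and 1.06 on the log2 scale, and Sparc, a collagen-binding protein, fell by 1.93. Centred on the array median the list had a median of 0.13 and Col4a2 gave 0.05, and the list was still called lower than other genes, with a median of 0.55 over all genes. Fibroblast markers averaged 0.55 lower (exact permutation test, adjusted p = 0.0204), with 1 rise, 6 falls and 5 not passing among 12, also adjusted over the list alone. They did not pass as a list (median -0.33, adjusted p = 0.101), and their median was -0.15 to 0.66 under the 4 other scalings. Of 12 ventricular cardiomyocyte markers 8 fell, 0 rose and 4 did not pass, also adjusted over the list alone (median -0.26, adjusted p = 1.69e-02, and adjusted p = 0.284 with an estimated correlation), with Mybpc3 at -0.73, Mb, which binds oxygen in muscle, at -0.57, Tnni3 at -0.49 and Ryr2 at -0.45. Mybpc3 and Ryr2 gave 0.03 and 0.53 when centred on the array median. Smooth muscle and pericyte markers fell in 7 of 11 cases, rose in 1 and did not pass in 3, also adjusted over the list alone (median -0.74, adjusted p = 3.13e-02, and adjusted p = 0.321 with an estimated correlation). Notch3 gave -1.49, Des -1.33, Smtn -1.31 and Cspg4 -1.15. Brown adipocyte markers rose in 5 of 8 cases, fell in 0 and did not pass in 3, also adjusted over the list alone (median 0.39, adjusted p = 9.43e-03, and adjusted p = 0.115 with an estimated correlation). Beside Ppargc1a these included Cidea at 1.05, Fabp3 at 0.57 and Cox8b at 0.49. Heart muscle itself expresses Ppargc1a, Fabp3 and Cox8b. Under the 4 other scalings neither of the last 2 lists was called, with medians of -0.76 to 0.06 for smooth muscle and -0.18 to 0.64 for brown adipocyte markers, and Fabp3 and Cox8b gave -0.42 and -0.21 in the values as deposited.

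The largest rises on the ketogenic diet were in Nr4a3, an early-response nuclear receptor (4.69 ± 0.62, adjusted p = 4.91e-06), Gpr160 (4.62), Tcf23 (4.38), Fam107a (4.09), Stk11ip (3.90), Amph (3.83), Osgin1 (3.63) and Hspa1a, a heat shock protein (3.62). The largest falls included the atrial genes Sln (-6.18 ± 0.89, adjusted p = 1.18e-05), Myl7 (-4.62) and Myl4 (-4.09), and Chad (-4.25), Smr2 (-3.89), Sec14l3 (-3.74), Foxf1 (-3.72) and Phgr1 (-3.63). Several of these genes are dim in the lower group, such as Nr4a3, Gpr160 and Tcf23 with fed means of 38.1, 13.2 and 11 or Chad with a ketogenic mean of 11, so the sizes and their order are uncertain. With an offset of the array median the rises gave 0.84 to 3.12 (Nr4a3 2.42, Gpr160 1.41, Tcf23 1.27) and the falls -3.62 to -1.04 (Sln -3.49). Other probe sets gave -0.39 for Foxf1 (adjusted p = 0.267) and -0.81 for Myl4 (adjusted p = 0.222), and Sec14l3 gave -0.60 without probe sets that may share sequence with other transcripts (adjusted p = 0.251). Atrial markers fell in 6 of 9 cases, rose in 0 and did not pass in 3, without passing as a list (median -1.46, adjusted p = 0.0852), and adjusted over the list alone 6 fell and 1 rose. Diet cannot be told apart from age, housing and processing note in these values, since each of these takes a single value within the ketogenic group.

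**Figure D3:**
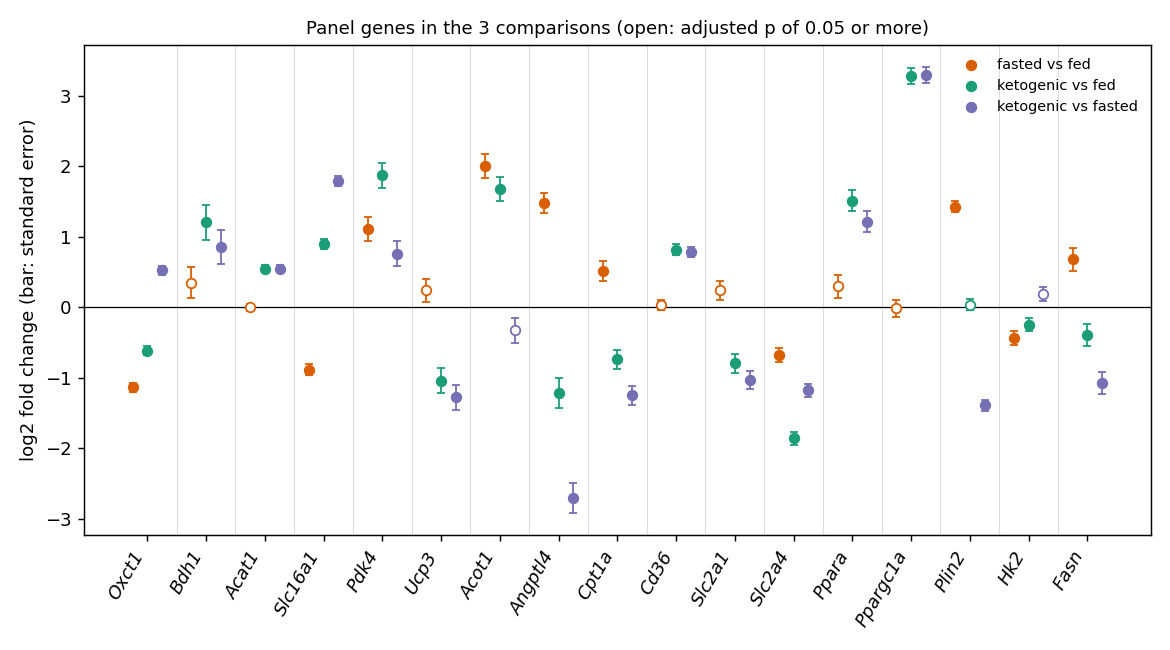
Log2 fold change with SE of the 17 tested panel genes in the 3 comparisons, with open points for an adjusted p of 0.05 or more. Ppargc1a stands at 3.28 in ketogenic vs fed and at -0.02 in fasted vs fed hearts, and Slc16a1 at 0.90 and -0.89.

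Ketogenic and fasted hearts were compared to ask whether both states, in which ketone bodies are a fuel, give the same transcripts, and they differed in ketone body, protein folding and atrial genes. With an estimated correlation none of these 3 lists passed (adjusted p = 0.1, 0.1 and 0.445). Of 6 ketone body genes 4 rose, 0 fell and 2 did not pass in ketogenic relative to fasted hearts, also adjusted over the list alone (median 0.98, adjusted p = 5.86e-03, and adjusted p = 0.1 with an estimated correlation). Slc16a1 was higher by 1.79 ± 0.07 (SE, n = 4 and n = 5, adjusted p = 7.06e-13), Bdh1 by 0.85 ± 0.25 (adjusted p = 6.78e-03), Acat1 by 0.55 and Oxct1 by 0.52 ± 0.06 (adjusted p = 7.57e-07). Without probe sets that may share sequence with other transcripts, of the same gene or another, Oxct1 gave -0.97 and the list did not pass (adjusted p = 0.162). Nor did the list pass when centred on the array median (adjusted p = 0.0529). Oxct1 gave 0.08 in the values as deposited (adjusted p = 0.364), and its other probe sets gave -0.97 to 3.40. Ppargc1a was higher by 3.29 ± 0.12 (adjusted p = 1.29e-13) and Plin2 lower, with a log2 fold change of -1.39 ± 0.08 (adjusted p = 2.44e-11). In all, 6627 of 12597 genes differed (2717 higher, 3910 lower), 2425 of them at least 2-fold (1119 higher, 1306 lower). The balance turned with the scaling, from 41% of called genes higher to 70.7% when centred on the array median. Normalized separately for each processing note, 77.6% were higher.

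Of 29 genes of the unfolded protein response and heat shock, 19 were higher, 5 lower and 5 did not pass on the ketogenic diet, also adjusted over the list alone (median 0.58, adjusted p = 9.41e-05, and adjusted p = 0.1 with an estimated correlation). Hsp90aa1 stood at 2.37, Dnajb9 at 1.77, Hsp90b1 at 1.67 and Hspb7 at 0.92 (-0.10 in the values as deposited). Oxidative stress defence was lower in 17 of 28 genes, higher in 5 and did not pass in 6, or lower in 18 and higher in 5 adjusted over the list alone (median -0.57, adjusted p = 2.45e-02, and adjusted p = 0.133 with an estimated correlation). Sod1 and Sod3, superoxide dismutases, gave -2.83 and -1.84, Txn2 -1.63 and Gstm1 -0.98. Normalized separately for each processing note, this list had a median of 0.03 and was not called. Extracellular matrix genes were lower in 21 of 30 cases, higher in 2 and did not pass in 7, also adjusted over the list alone (median -0.78, adjusted p = 2.07e-04, and adjusted p = 0.485 with an estimated correlation). Elastin (Eln) stood at -2.89, Bgn at -1.54, Col6a1 at -0.86 and Col4a2 at -0.60 (0.22 when normalized separately for each processing note). Fibroblast markers averaged 0.35 lower (exact permutation test, adjusted p = 0.0239), with 4 higher, 6 lower and 2 not passing among 12, or 4 and 7 adjusted over the list alone, and did not pass as a list (median -0.55, but 0.21 when normalized separately for each processing note, adjusted p = 0.6). Other marker means were lower as well, by 0.86 for smooth muscle and pericytes, 0.43 for endothelium, 1.97 for white adipocytes and 1.05 for skeletal muscle (exact permutation test, adjusted p = 0.013 for each). The endothelial list median turned with the scaling, from -0.21 to as much as 0.55. Ribosomal protein genes were higher in 17 of 34 cases, lower in 10 and did not pass in 7, also adjusted over the list alone (median 0.23, adjusted p = 1.70e-02, and adjusted p = 0.445 with an estimated correlation). Rps20 stood at 1.58, Rps10 at 1.23, Rps29 at 1.08 and Rplp0 at 0.67. The ribosomal median was -0.15 and Rps29 -0.35 in the values as deposited. All 9 atrial markers were lower, also adjusted over the list alone (median -3.83, adjusted p = 5.85e-04, and adjusted p = 0.445 with an estimated correlation), among them Dkk3 at -5.16 and Stard10 at -3.04.

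Panel genes of fat and glucose use differed from fasted hearts in both directions, beside white adipocyte markers that averaged 1.97 lower. The PPAR-responsive list did not pass after quantile normalization, with 5 higher, 11 lower and 8 not passing among 24, also adjusted over the list alone (median -0.39, adjusted p = 0.221), but passed under the 4 other scalings (-0.95 to -0.24). So did ventricular cardiomyocyte markers, with 3 higher, 6 lower and 3 not passing among 12, also adjusted over the list alone (median -0.19, adjusted p = 0.589), and -1.45 to -0.50 under the other scalings. Angptl4 gave -2.70 ± 0.21 (adjusted p = 3.99e-09), Ucp3 -1.28, Fasn -1.07 and Slc2a4 -1.18, while Ppara was higher by 1.21 and Cd36 by 0.78. Cd36 gave 0.09 in the values as deposited (adjusted p = 0.3) and 0.12 without probe sets that may share sequence with other transcripts (adjusted p = 0.391). The other probe set of Slc2a4 gave -0.05 (adjusted p = 0.571), and Angptl4 gave -0.93 with the mean of all its probe sets (adjusted p = 0.134). Cpt1a gave -1.25 and Slc2a1 -1.04, but 0.44 and 0.20 with the mean of all their probe sets. Pdk4 gave 0.76 (adjusted p = 1.22e-03), but -0.31 in the values as deposited, and Acot1 gave -0.33 (adjusted p = 0.121, and 0.45 when normalized within each processing note) and Hk2 0.19 (adjusted p = 0.119). The largest rises were in Ell2 (4.45 ± 0.71, adjusted p = 2.98e-05), D130051D11Rik (3.99), Fbxo22 (3.70), Rgcc (3.61), Klhl2 (3.60), Ifi207 (3.34), Zfp935 (3.31) and Ppargc1a. Other probe sets gave -0.03 and 0.76 for Fbxo22 (adjusted p = 0.917 and 0.516) and 0.43 for Rgcc (adjusted p = 0.0255). The largest falls were in the atrial genes Sln (-10.56 ± 0.89, adjusted p = 9.12e-09), Myl7 (-8.19), Myl4 (-7.53) and Mybphl (-5.47), and in Mlana (-5.89), Car3 (-5.73), Tmem163 (-5.60) and Chad (-5.42). Ketogenic means of Sln (34.9), Mlana (12), Tmem163 (16.4) and Chad (11) are too dim to fix the size of these falls or their order. With an offset of the array median the falls gave -7.67 to -2.01 (Sln -7.67) and the rises 0.93 to 3.37. Other probe sets gave -1.07 for Myl4 (adjusted p = 0.108) and -2.70 for Car3. Without fasted sample 4, Zfp935 gave 2.13 (adjusted p = 0.0647), and it did not pass without any 1 ketogenic sample either (adjusted p = 0.0779 to 0.0995). With the atrial marker mean as a covariate, 1668 genes passed in place of 6627, and the extracellular matrix median was 0.0023.

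Fasting and the ketogenic diet changed 1632 genes in the same direction against fed hearts, 764 of them higher and 868 lower, and 1032 genes in opposite directions. The split into higher and lower depends on the scaling. Centred on the array median, 83.1% of all calls after the fast and 85.2% of those on the ketogenic diet were higher. Independent lists of these sizes would give 476 genes higher in both, 581 lower in both, and 630 and 439 in opposite directions. Of the opposite genes, 518 were higher after the fast and lower on the diet, below the 630 of independent lists. The other way round there were 514, above the 439 of independent lists. Both comparisons share the fed arrays. With these split between the comparisons in 20 ways, the same-direction count had a median of 1148 (961 to 1281), against 808 for independent lists. Among the named genes, those that moved the same way included Pdk4, Acot1, Mt1 and Bnip3 (higher) and Slc2a4 and Pgk1 (lower), whereas Slc16a1, Angptl4, Fasn and Cpt1a went opposite ways. For these 4 the difference between ketogenic and fasted hearts itself passed the test, and under other scalings Fasn and Cpt1a gave 0.21 and 0.19 on the ketogenic diet. Of the 6283 genes changed on the ketogenic diet against fed hearts, 4296 (68.4%) differed the same way from fasted hearts, 1733 of them higher and 2563 lower than in both other groups.

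**Figure D4:**
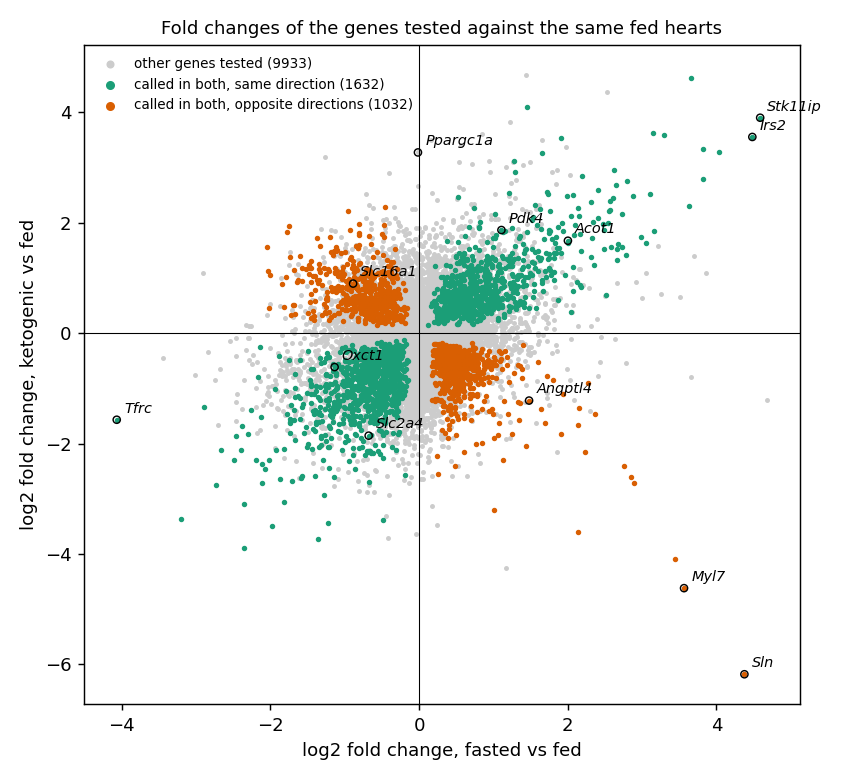
Log2 fold change of each tested gene in ketogenic vs fed hearts against fasted vs fed hearts, 1 point per gene, with genes changed in both comparisons coloured by direction. Of these, 1632 changed in the same direction and 1032 in opposite directions.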

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

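The tests of both explanations for the atrial markers, of the size of the fold changes with the atrial covariate, of study against diet, of probe sets of 1 gene and of calls kept under other normalizations were chosen only after the results were seen.

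Atrial markers averaged 2.76 log2 units higher in fasted than in fed hearts, with all 5 fasted samples above all 5 fed samples (exact permutation p = 0.00794, adjusted p = 0.0238). A candidate explanation is that the fasted pieces held more atrium: over the 5 fed samples alone, the markers tended to rise and fall together, with a median pairwise r of 0.636 (0.548 to 0.816 with 1 fed sample left out). Bmp10, dim in fed hearts, did not follow them. Its log2 signal was highest in fed sample 3 (6.203, others 4.816 to 5.038), and the marker mean in fed sample 1 (12.11). With the atrial marker mean as a covariate, the log2 fold change of Bmp10 after the fast went from 3.86 to 4.00. That of Sln went from 4.38 to -0.61. Whether the fast itself raised atrial genes stays open. The range of the marker mean over fed samples was 1.22 times the group difference but 0.505 times it without fed sample 1. This range shows how far the markers vary without a fast. It cannot decide the question, since unequal atrium and an effect of the fast can hold at once. These explanations cannot be told apart, because the share of atrium in each piece was not recorded in the labels. White adipocyte markers, higher by 1.56 on the mean, moved with them.

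Between fasted and fed hearts 4262 genes changed, 1017 of them at least 2-fold, and the highest count in the other splits was 0 for both. Only the real one of 100 splits reached these counts. This argues against chance but does not exclude it, since 1 of 100 is the smallest share these splits allow. For lists, 14 passed and 6 of 100 splits gave as many (highest other 15). Apart from the real one, these splits have 1 sample of each group exchanged, with the group names swapped. They hold most of the real contrast, so this count does not decide whether chance could give as many lists. With the atrial mean as a covariate 25.7% of the calls were kept. The median fold of called genes went only from 0.664 to 0.653, while their median SE rose from 0.136 to 0.265. The atrial mean does not overlap between fed (up to 12.11) and fasted hearts (from 12.49), so these folds rest on a slope extended beyond each group. The fit therefore cannot settle how much an unequal share of atrium contributed. For atrial markers the median went from 3.10 to -0.38, which follows in part because the covariate is their own mean. The median went from 2.07 to 0.38 for white adipocyte markers and from 1.03 to -0.04 for skeletal muscle markers. It also shrank for PPAR-responsive genes (1.05 to 0.73) and triglyceride storage (0.90 to 0.62). RNA preparation as marked by 18S stays open. The slope on 18S within groups correlated with the fold changes at r = -0.00704 across called genes (52 of 100 permutations were at least as high). However, 18S had an SD of only 0.53 in fed and 0.62 in fasted hearts, against a difference of 2.82 between them without overlap. A test within groups may therefore miss such an effect. The ratio of 3' to 5' probe sets of Gapdh, 0.823 in fed and 0.989 in fasted hearts, was not tested in this way. The fast stays open as the hypothesis for the changes that kept their size, and the covariate leaves too little precision to sort single genes.

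Ketogenic hearts differed from fed hearts in 6283 genes and 2055 at least 2-fold (highest other split 4325 and 1196). From fasted hearts they differed in 6627 and 2425 (4745 and 1495). Each count was reached by 1 of 100 splits, the real one, which argues against chance but does not exclude it. For lists, 12 of 100 splits gave at least the 10 of the first comparison (highest other 15). In the second, 7 of 100 gave at least 6 (highest other 7). Several of these splits exchange only 1 ketogenic sample and hold most of the real contrast. These list counts therefore do not decide whether chance could give as many. Normalization between arrays stays open. Of the genes called higher than in fed hearts, 82.2% were called higher under all 4 other normalizations (30.1% for those called lower). Median centring and normalization within each processing note raise all genes (median 0.55 and 0.43), which by itself keeps higher calls. The values as deposited lower all genes (median -0.26) and still kept 82.2% of the higher calls. A downward shift of that size therefore does not remove most of them. The lowest count under another normalization, 7324, decides nothing, since a shift of all genes raises counts. Of the genes that differed from fed hearts, 68.4% differed the same way from fasted hearts, a share that the shared ketogenic arrays raise. Another study, age, housing or RNA preparation could give it as well as the diet, and these cannot be told apart because each coincides with the diet. Bias between probe sets of 1 gene stays open too: 23.5% of the pairs called in both went opposite ways (24.1% in fasted vs fed), and dimmer probe sets lay 0.211 above the brightest (0.0176 in fasted vs fed). No test here separates a response to the diet from these.

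Samples far from the rest of their group were looked for in 240 groups of values, and 18 stood apart, where chance alone would give 12. The deposited median signal of fed sample 5 was 207 (other fed samples 148 to 163.3) and that of fasted sample 1 was 117 (others 136 to 138.9). The mean correlation with the other samples of the group was 0.9167 for fed sample 5 (others 0.9408 to 0.9456) and 0.9331 for fasted sample 5 (others 0.9372 to 0.9387). The white adipocyte mean was 9.217 in fasted sample 1 (others 9.795 to 9.995) and 7.006 in ketogenic sample 2 (others 7.988 to 8.131), and the brown adipocyte mean was 11.56 in fasted sample 1 (others 11.78 to 11.84). Among single genes on the log2 scale, fed samples stood apart for Gm20346 (6.461 in sample 4, others 3.058 to 3.464), Bmp10 (6.203 in sample 3, others 4.816 to 5.038) and Ell2 (5.996 in sample 5, others 7.684 to 8.088). Fasted samples stood apart for Hspa1a (4.3 in sample 2, others 6.641 to 7.271), Foxf1 (6.3 in sample 4, others 8.066 to 8.677), Ell2 (2.743 in sample 5, others 6.342 to 7.589), Zfp935 (-0.4781 in sample 4, others 4.703 to 6.044) and Car3 (8.64 in sample 1, others 10.38 to 10.76). Ketogenic samples stood apart for Exoc3l2 (5.498 in sample 3, others 6.998 to 7.267), Amph (7.765 in sample 3, others 7.603 to 7.616) and Fbxo22 (11.43 in sample 4, others 11.64 to 11.66).

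For 4 panel genes fasting and the ketogenic diet moved the signal against fed hearts in opposite directions, and the difference between both effects was tested as ketogenic vs fasted. This difference was 1.786 for Slc16a1 (-0.89 fasted, 0.90 ketogenic), -2.702 for Angptl4 (1.48 and -1.22), -1.25 for Cpt1a (0.51 and -0.74) and -1.071 for Fasn (0.68 and -0.39). These are values of the brightest probe set: with the mean of all probe sets the difference was 0.44 for Cpt1a and -0.93 for Angptl4 (adjusted p = 0.134), and the change of Slc16a1 after the fast was 0.015. In such a mean, dim probe sets weigh as much as bright ones, and the other probe sets of these genes are dim. With the atrial covariate Fasn gave 0.37 after the fast (adjusted p = 0.541). Outside the main measurement, the control probe sets for 18S ribosomal RNA were 7.05-fold higher in fasted than in fed hearts, in 5 of 5 samples.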

How the results depend on the processing

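The atrial covariate, and leaving out fed samples 1 and 5 together, were chosen after seeing the data. Over the settings other than leaving out 1 array, including those, directions and calls of named genes held in 538 of the values for fasted vs fed, 547 for ketogenic vs fed and 526 for ketogenic vs fasted, with calls lost in 25, 21 and 23, gained in 14, 4 and 8, and directions reversed in 4, 10 and 12. Leaving out 1 array at a time, they held in 456, 447 and 441 values. Calls were then lost in 6, 15 and 5, and gained in 2 for ketogenic vs fasted. With 1 array left out, genes changed numbered 3745 to 4264 (fasted vs fed), 5587 to 6392 (ketogenic vs fed) and 6028 to 7005 (ketogenic vs fasted), those changed at least 2-fold 936 to 1035, 1904 to 2119 and 2274 to 2531, lists 13 to 15, 10 to 12 and 6 to 7, and genes changed the same way by both 1458 to 1572. Without fed samples 1 and 5, 3690, 5943 and 7067 genes changed. Dim probe sets limit what can be seen, as 5596 genes lay too low to test.

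Scaling moved counts and directions. As deposited, 3126 genes changed at least 2-fold in ketogenic vs fed hearts and 10 lists passed in ketogenic vs fasted. Reversed values were glycolysis -0.0165 (above -0.0676 for all genes) and tricarboxylic acid cycle 0.227 in fasted vs fed, Hk2 0.04484 in ketogenic vs fed, and Pdk4 -0.3134 and ribosomal proteins -0.152 in ketogenic vs fasted. Centred on the array median, the counts were 4098, 10 and, for genes changed the same way, 2837. In fasted vs fed Hk2 gave 0.07855, glycolysis 0.303, pyruvate dehydrogenase 0.273 and the tricarboxylic acid cycle 0.546, and in ketogenic vs fed Oxct1 gave 0.1165, Cpt1a 0.1853, Hk2 0.8612 and Fasn 0.2072. Centred on the 75th percentile, 10 lists passed in ketogenic vs fasted, with glycolysis at 0.0995, pyruvate dehydrogenase 0.0695 and tricarboxylic acid cycle 0.343 in fasted vs fed, Hk2 0.2219 in ketogenic vs fed, and Pdk4 -0.2524 and ribosomal proteins -0.091 in ketogenic vs fasted. Normalized within each processing note, 3440 genes changed at least 2-fold in ketogenic vs fed, Hk2 gave 0.5941 and Fasn 0.1076, and Acot1 gave 0.4523 in ketogenic vs fasted. Measured from the median of all genes, Cpt1a (-0.446 to -0.369), Fasn (-0.347 to -0.325) and Oxct1 (-0.745 to -0.438) in ketogenic vs fed, Hk2 in fasted vs fed and ribosomal proteins kept their direction, so these reversals go with a shift of all genes. Hk2 in ketogenic vs fed (0.161 to 0.307), Pdk4 and Acot1 in ketogenic vs fasted and the 3 lists in fasted vs fed turned even so, and for these the cause was not tested.

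An offset of the median shrinks folds by construction and left 409, 925 and 1342 genes at least 2-fold in fasted vs fed, ketogenic vs fed and ketogenic vs fasted. The filter at the 70th percentile tests fewer genes and left 646 in fasted vs fed. At an adjusted p below 0.01, 2702 genes changed in fasted vs fed and 920 the same way in both. With an estimated correlation 5, 1 and 0 lists passed, and with fry 22, 36 and 34. With the mean of all probe sets, Slc16a1 gave 0.01456 in fasted vs fed, Cpt1a 0.4635 and Slc2a1 0.3841 in ketogenic vs fed, and Cpt1a 0.4436 and Slc2a1 0.1982 in ketogenic vs fasted. Without probe sets prone to shared sequence Oxct1 gave -0.9656 in ketogenic vs fasted. For these genes the cause was not tested.

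With the atrial covariate, 1181 genes changed in fasted vs fed (572 at least 2-fold), 3797 in ketogenic vs fed, 1668 in ketogenic vs fasted (1338) and 320 the same way in both. The atrial mean does not overlap between the groups. In fasted vs fed the median SE of called genes rose from 0.136 to 0.265, while that of atrial markers fell from 0.490 to 0.341. Reversed in fasted vs fed were Mlana -0.01753, Sln -0.6138 and the atrial list -0.614, and in ketogenic vs fasted Ifi207 -1.85, Zfp935 -1.894, Myl7 0.2067, Myl4 0.03742, Mlana 2.189, Tmem163 1.313, the extracellular matrix list 0.00225 and the atrial list 0.0374. For Ifi207 and Zfp935 the cause was not tested.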

Other observations

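Single genes outside the main account also changed, in lists that did not pass as groups after quantile normalization. Contractile and fetal-programme genes gave 8 rises and 6 falls among 23 after the fast (also adjusted over the list alone, camera adjusted p = 0.81, though the list passed under 3 of the 4 other scalings, with medians up to 0.97), with Myh7, the slow myosin of the fetal ventricle, up by 2.51 (adjusted p = 1.15e-07) and Myh6, the adult form, at -0.62 (adjusted p = 5.84e-07), or 0.38 when centred on the array median. Myl4, Myl7 and Nppa of the contractile list are also atrial markers. With the atrial marker mean as a covariate, the median fold of its called members after the fast went from 0.57 to 0.34. Clock genes gave 3 rises and 4 falls among 19 after the fast and 6 rises and 4 falls on the ketogenic diet, also adjusted over the list alone (camera adjusted p = 0.9 and 0.543). The repressor Nr1d2 was -1.14 after the fast and 0.81 on the diet, and Nr1d1 -0.69 and -2.15, while the times of day at which hearts were taken are not given in the sources used here. Genes of branched-chain amino acid catabolism gave 4 rises and 11 falls among 22 on the ketogenic diet, also adjusted over the list alone (median -0.18, adjusted p = 0.307), but the median was 0.07 to 0.89 under the 4 other scalings, 1 of which called the list, with the transaminase Bcat2 at -1.92.

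On the ketogenic diet, 11 of 21 ion channel genes were lower and 4 higher, also adjusted over the list alone (median -0.31, but up to 0.60 under other scalings, adjusted p = 0.0746), among them the potassium channel genes Kcnj11 at -1.88, Kcnh2 at -1.50, Kcnip2 at -1.42 and Kcnk3 at -1.31. Of 24 interferon-stimulated genes 11 were lower and 0 higher, also adjusted over the list alone (median -0.41, but up to 0.17 under other scalings, adjusted p = 0.0746), with Igtp at -1.30, Irf7 at -1.18 and Tap1 at -1.09. The mean of T and B lymphocyte markers was 9.52 in fed, 8.92 in fasted and 8.60 in ketogenic hearts, lower than in fed hearts by 0.61 after the fast and by 0.93 on the diet, with every fasted and every ketogenic sample below every fed sample (exact permutation p = 0.00794 for each, adjusted p = 0.0238 and 0.0204). Only 6 of 14 such markers were tested, with 0 rises, 2 falls and 4 not passing after the fast (camera adjusted p = 0.151, the same adjusted over the list alone) and 0, 3 and 3 on the diet (camera adjusted p = 0.166, with 4 falls adjusted over the list alone). Endothelial markers were lower by 0.41 in ketogenic than in fed hearts (adjusted p = 0.0204, 4 of 4 samples), but as a list they did not pass (median -0.14, adjusted p = 0.296, 2 rises, 7 falls and 5 not passing among 14, or 3 rises and 7 falls adjusted over the list alone), and the median was 0.02 to 0.83 under the 4 other scalings.

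Iron uptake was covered by no list, and the fall of Tfrc after the fast was seen in all 4 of its probe sets. Whether ketogenic hearts differ from hearts of fed mice of the same age and housing was not tested, since no such sample is in the series.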
